A study of Drosophila melanogaster with 3 samples.

How the data were processed

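The measurements were peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Drosophila melanogaster embryos of mixed sex, collected whole at 0 to 16 hours. The flies carried a transgene in which the protein of the gene ind (intermediate neuroblasts defective) ended in eGFP, a green fluorescent protein, and per the labels an antibody against GFP pulled down the chromatin. Per the labels, the chromatin was sonicated, with a size range of 200 to 800, and the 3 samples were 3 biological replicates from separate biosamples. All 3 belonged to 1 group, so no comparison between groups was made. Samples are named by the biological replicate numbers in the labels.

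Per the notes deposited with the lists, the authors made a relaxed list of peaks and background for each replicate from its own alignment and 1 control. They made a pooled relaxed list from the alignments of all 3 replicates and the control. From the 3 replicate lists and the pooled list they derived an optimal list by the irreproducible discovery rate, a measure of how well peaks keep their rank between replicates. Each of these lists came in the genome builds dm6 and dm3. The aligner, the peak caller and their versions are not given in the sources used here. The control's own data were not analysed here, and neither were the alignments or signal tracks. The signal value of each peak is the authors' own, as deposited in the lists, and was used only to describe, rank or filter peaks within a list. The q-value of each peak is deposited on the −log10 scale by the layout of the lists. It stood at a shared maximum of 4.08 in all 5809 optimal peaks and therefore ranked nothing among them. Read depth is not given in the lists, so the depth of each replicate is unknown and no interval that needs it is given. All 5809 optimal peaks of dm6 were found in the pooled list, where the lowest of them ranked 5809 of 24244. The optimal list was thus the strongest part of the pooled list.

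Positions are 1-based in dm6. The dm6 lists were joined to the reference sequence of the same assembly and to the Ensembl BDGP6 annotation, and no peak of the dm6 lists lay outside the arms used. The dm3 lists served only for counts and overlaps within that build. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, on the arms 2L, 2R, 3L, 3R, 4, X and Y.

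A peak was represented by its summit. An optimal peak counted as found in a replicate when 1 of that replicate's 5809 strongest peaks (as many as the optimal list holds) had its summit within 200 bp. No minimum overlap of intervals was required except in 1 alternative, where intervals had to overlap by 50% of both. Chance overlap came from 100 random circular shifts of the replicate's summits within each arm. A promoter was the 500 bp on each side of any annotated transcription start, coding or not. Summits elsewhere were assigned in the order 5' UTR, CDS, 3' UTR, intron (which here also takes exons of non-coding genes) and intergenic. Shares were compared with 1000 circular shifts of the summits, which keep the spacing of the peaks, by a two-sided permutation p.

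A gene counted as having a peak when a summit lay in its body or up to 2000 bp upstream, so 1 peak can count for overlapping or neighbouring genes. The 15 gene lists, the motifs, the tests and the rule for named genes were fixed before the data were examined. For each list the share of genes with a peak was compared with 10000 random lists of protein-coding genes matched gene by gene on length in 20 bins. The two-sided permutation p was adjusted by Benjamini-Hochberg over the 15 lists. Older symbols were matched to current ones through a table of synonyms and a short map of 5 names written after the annotation was seen. The spellings slit, RpII215 and don-juan stayed unmatched, and their genes were counted under the symbols sli, Polr2A and dj, which the lists also gave. Motifs were sought on either strand within 100 bp of each summit and in windows of the same width 1000 bp to each side. Their p came from 100000 random sign swaps of each peak's difference between the summit window and the mean of both flanks, adjusted over 10 fixed 6-mers. All 2080 6-mers were ranked by ratio without a test.

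The genes named were ind itself, the genes nearest to or holding the 25 strongest optimal peaks found in all 3 replicates, up to 4 genes per list with the strongest peak, and the genes nearest to the 2 strongest peaks per replicate with no summit within 500 bp in the other lists. Any other gene or 6-mer named was chosen after its values were seen. A relative signal is a peak's signal divided by the median of the same list. Its replicate values divide the matched peak's signal by the median of the peaks matched in that replicate. Means are given with the SD over replicates, n = 3, and p-values over peaks or genes describe these lists, since peaks and genes are not replicates of the experiment. Tests were two-sided.

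The statistics were tested on simulated data. Among lists of 30 genes, the list test called 3 of 50 lists with no effect and 50 of 50 in which 60% of genes had been given a peak. The motif test on 5809 peaks called 0 of 20 sets with no effect and 20 of 20 with TAATTA written into 6% of windows. The promoter test called 0 of 10 sets with no effect and 10 of 10 with 20% of summits moved to a start. These simulations placed peaks at random over the arms and drew genes at random. They do not show the power for smaller effects or for lists of long genes. Nor do they test motif calls where summits and flanks differ in base composition, as the real ones do. Alternatives were other peak thresholds, each replicate left out in turn, other distances and windows, other assignments of peaks to genes, the list without length matching and the dm3 lists. The 3 kinds added after seeing the data were promoter peaks alone, peaks outside promoters alone, and 1 peak per 500 bp. Families of genes taken by symbol, base composition checks and longer sequence words were also chosen after seeing the data. With 3 samples no test for an outlying sample was run. The background of the tagged-protein ChIP was judged only by the authors' use of the control in their calls, and no control lists were used here.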

Results

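Binding of the ind-eGFP protein was mapped by ChIP-seq in 3 biological replicates of whole Drosophila embryos aged 0 to 16 hours. The gene ind encodes a homeodomain transcription factor of the intermediate column of the embryonic nerve cord primordium. The authors' optimal list held 5809 peaks in dm6, covering 1.85 Mb with a median width of 400 bp. The relaxed lists held 24244 peaks for the pooled reads, 30000 for replicate 1, 27570 for replicate 2 and 25725 for replicate 3. The list of replicate 1 held exactly 30000 peaks in dm3 as well, and whether its length was limited in the processing is not given in the sources used here. Peaks with a −log10 q-value of at least 2 numbered 11218 in replicate 1, 6134 in replicate 2 and 8413 in replicate 3. Read depth is unknown. The signal of the optimal peaks ran from 118.7 to 5944 with a median of 219.2.

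The first question was how far each replicate held the sites of the optimal list, which the authors had chosen for their consistent rank in these same replicates, so that high overlap and rank correlation are partly built in. On average 87.3% ± 5.77 (SD, n = 3) of the optimal peaks had a summit within 200 bp among a replicate's 5809 strongest peaks. The share was 80.8% in replicate 1, 89.3% in replicate 2 and 91.8% in replicate 3. Shifted summits overlapped by 1.71%, 1.70% and 1.71% on average, and by at most 2.29% (permutation p = 0.0099 in each replicate, the smallest that 100 shifts can give). In total 4071 optimal peaks (70.1%) were found in all 3 replicates, 1278 in 2, 444 in 1 and 16 in 0. Of the strongest 1453 peaks 99.7% were found in all 3, against 14.8% of the weakest 1452. Weak optimal peaks lie near the edge of each replicate's 5809 strongest, which by itself lowers their share. For rank correlation, peaks were matched within 200 bp in each replicate's full relaxed list. Their signal ranked the sites with a Spearman rho of 0.772 between replicates 1 and 2, 0.779 between 1 and 3 and 0.868 between 2 and 3. These correlations are across peaks, which are not independent replicates.

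**Figure D1:**
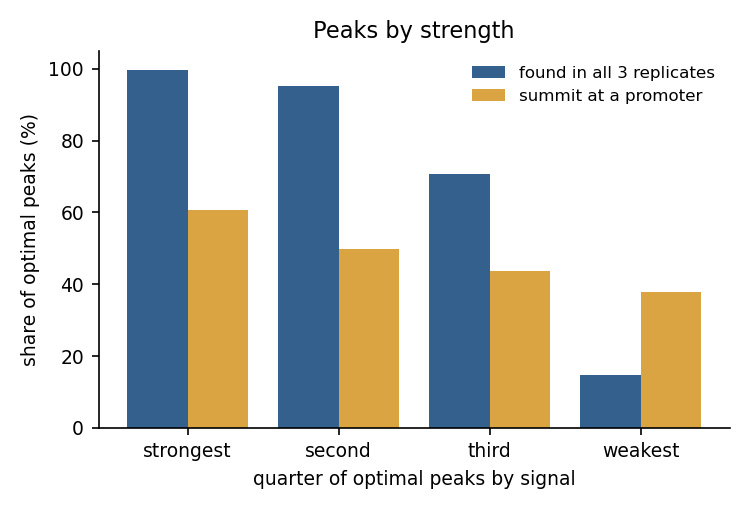
Share of optimal peaks (%, vertical axis) in 4 equal parts of the list by signal (horizontal axis), from strongest to weakest: blue bars give peaks found in all 3 replicates and yellow bars give summits within 500 bp of a transcription start. Blue bars go from 99.7% in the strongest to 14.8% in the weakest part, and yellow bars from 60.8% to 37.9%.

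The ind gene itself (FBgn0025776, 3L from 15042799 to 15043924, minus strand) held 0 optimal peaks and 0 pooled relaxed peaks in its body and 2000 bp upstream. A single relaxed peak in replicate 2 lay in this region, at rank 8071 of that replicate's list, and replicates 1 and 3 had 0. The optimal list had 4 peaks within 20000 bp of ind. All 4 lay within Sytbeta, a synaptotagmin gene that spans ind. Their summits were at 8279, 9245 and 9444 bp from the ind start, counted in the direction of its transcription, and at -10462 bp, where the nearest start was that of CG18649. The strongest of the 4 (3L from 15034280 to 15034679) was at a Sytbeta promoter and had a signal 1.38 times the list's median (1.41 ± 0.280 in the replicates, SD, n = 3).

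The signal of a peak is the authors' own value and is given here relative to the median of the same list. The strongest peak (X from 2703663 to 2704117) had its summit at -24 bp from a start of Ugalt, a UDP-galactose transporter, with a signal 27.1 times the list's median and 26.3 ± 3.66 times in the replicates (SD, n = 3). The second (3L from 19590393 to 19590843) lay at -96 bp from the start of CG14100, at 23.6 times the median (22.9 ± 3.17, SD, n = 3). The third (2L from 480848 to 481311) lay in an intron of ush, which encodes a cofactor of GATA factors, at -1366 bp from the nearest start, that of cbt, at 19.8 times the median (19.1 ± 2.83, SD, n = 3). The fourth (2L from 6612474 to 6612928) lay in an intron of CG11050 at 15.5 times the median (15.3 ± 0.783, SD, n = 3).

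Of the 25 strongest peaks found in all 3 replicates, 19 had their summit at a promoter and 6 did not, and all had relative signals between 10.4 and 27.1. Promoter peaks of this set lay at Chro (a chromosomal and spindle protein, relative signal 15.1), mRpL41 (a mitochondrial ribosomal protein, 14.9), ph-p (a Polycomb group protein, 14.7), Art3 (an arginine methyltransferase, 14.5), CenG1A (13.7) and Tcs5 (13.4). Others lay at px, PNPase, CG1888, eIF6 (a ribosome biogenesis factor, with the summit in ytr), CG5611, Pal1, Atat (a tubulin acetyltransferase), GstE13, larp and CG5098, with relative signals from 10.4 to 12.7. The peak nearest to CG4004 among coding genes stood at the start of a non-coding gene, 5110 bp from the coding start. Outside promoters were, besides those in ush and CG11050, the peaks at Lk6, tara, CG32772 and HmgZ. The 25 peaks' nearest coding genes included 0 members of the 15 gene lists, although the peaks in ush and upstream of Mef2 (beside Pal1) counted for those list genes by position. The homeodomain core TAATTA lay within 100 bp of 5 of the 25 summits.

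Peaks were concentrated at promoters. Within 500 bp of a transcription start lay 2792 summits, 48.1% of the list, against 13.6% of shifted summits, a 3.54-fold excess (permutation p = 0.001, the smallest that 1000 shifts can give). The replicates' own 5809 strongest peaks gave 48.9% ± 3.45 (SD, n = 3), with 52.6% in replicate 1, 45.8% in replicate 2 and 48.2% in replicate 3. The promoter share was 60.8% in the strongest 1453 peaks and 37.9% in the weakest 1452. Coding sequence held 11 summits (0.189%), against 13.7% of shifted summits. The 3' UTRs held 54 summits (0.930% against 4.44%) and 5' UTRs beyond the promoter window held 22 (0.379% against 0.777%). Introns held 2150 summits (37.0% against 40.4%) and intergenic sequence 780 (13.4% against 27.1%). Each of these shares lay below that of shifted summits (permutation p = 0.001 for each, the smallest possible), and since all shares sum to the whole list, the promoter share lowers the others. Among the 3017 summits outside promoters, examined after seeing the data, introns held 71.3% against 46.7% of shifted summits and intergenic sequence 25.9% against 31.4%, with coding sequence at 0.365% against 15.8% (permutation p = 0.001 for each, the smallest possible). The median distance from a summit to the nearest start was 555 bp, and 1078 summits (18.6%) lay within 100 bp of it.

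**Figure D2:**
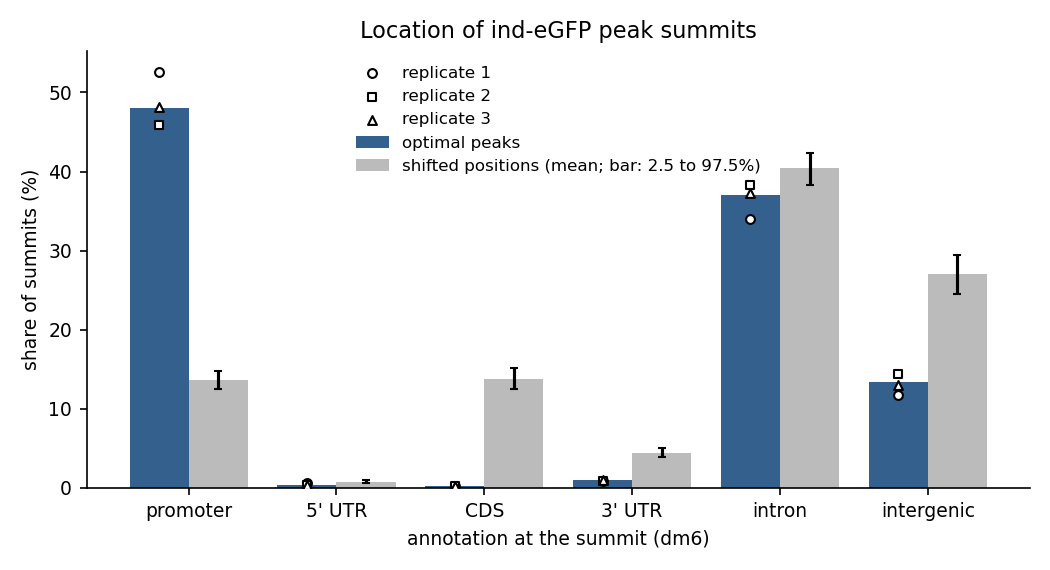
Share of peak summits (%, vertical axis) by annotation at the summit in dm6 (horizontal axis): blue bars are the 5809 optimal peaks, grey bars the mean of 1000 circular shifts with error bars for the middle 95%, and open symbols the 3 replicates' own strongest peaks. Promoters held 48.1% of summits against 13.6% of shifted ones, and coding sequence 0.189% against 13.7%.

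Among chromosome arms, the X had 49.5 peaks per Mb, 2L 45.5, 3R 42.9, 3L 42.4 and 2R 39.2. The fourth chromosome had 11.9 peaks per Mb (16 peaks) and the Y had 0 peaks. Peak density on the X was 1.18 times that of the autosomes together (1166 peaks against 4643, two-sided exact binomial p = 9.8e-07). The ratio was 1.16 ± 0.0827 (SD, n = 3) over replicates, with 1.06 in replicate 1, 1.22 in replicate 2 and 1.19 in replicate 3. The binomial test takes peaks as independent, and neighbouring peaks are not. All densities used the full length of each arm in dm6, whatever part of it can hold peaks. The copy number of the X in embryos of mixed sex was not taken into account. The ratio therefore describes the list and cannot be read as stronger binding on the X.

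The gene lists asked whether neural patterning genes, the textbook setting of ind, more often carried a peak than length-matched genes. Ribosomal protein genes and housekeeping genes did so, and the neural lists did not. The number of peaks per gene was not tested. Of 35 ribosomal protein genes 28 had a peak (80.0%), against 27.7% in matched lists (adjusted permutation p = 0.00075, from the smallest p that 10000 lists can give). The replicates gave 81.9% ± 8.25 (SD, n = 3), and for each of the 5 lists that passed, 3 of 3 replicates lay on the same side of the expected share. Of the 32 peaks at ribosomal protein genes 30 were at promoters, led by RpL32 (relative signal 4.58), RpS27 (4.00), RpL7 (3.57) and RpL14 (2.08). The RpL32 peak lay nearest to the start of CG7943, which starts beside RpL32 on the other strand. Of 24 housekeeping genes 19 had a peak (79.2%), against 39.4% in matched lists (adjusted permutation p = 0.00075), with 77.8% ± 2.41 in the replicates (SD, n = 3). They were led by the small heat shock protein gene Hsp27 (relative signal 7.09) and the glycolytic enzyme genes Gapdh2 (5.91), Eno (3.96) and Pgk (2.91). The list fixed as housekeeping also holds heat shock genes, so it is not made of steadily expressed genes alone. Of these Hsp26, Hsp27 and Hsp83 had a peak, and Hsp70Aa and Hsp70Ba did not. The call for housekeeping genes was not kept when each peak went to the nearest start alone (50% against 29.4%, adjusted permutation p = 0.13). With peaks outside promoters alone, 0 of the 15 lists passed the test in either direction, and 2 had an unadjusted permutation p under 0.05 (mesoderm and muscle above, temporal and motor neuron identity below). With promoter peaks alone, dorsoventral columnar genes stood at 16% against 36.6% (unadjusted permutation p = 0.036, adjusted 0.077), endoderm, fat body and haemocyte genes at 11.1% against 35.3% (unadjusted 0.049, adjusted 0.092) and Hox genes at 14.3% against 38.2% (unadjusted 0.099, adjusted 0.15). Segment polarity genes stood at 17.4% against 36.0% (unadjusted permutation p = 0.078, adjusted 0.13). Temporal and motor neuron identity genes passed below the expected share there (8.33% against 38.3%, adjusted permutation p = 0.007).

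The list of dorsoventral columnar patterning, which holds ind and its neighbours vnd and Dr, did not pass the test. It also holds genes not confined to the neural columns, such as the signalling genes spi, aos and dpp and the genes zen, pnr and Doc1. The genes ind, vnd, Dr, SoxN and D had 0 optimal peaks, so the share of this list came from its other members. Of its 25 genes 12 had a peak (48.0% against 52.1%, adjusted permutation p = 0.98), with 53.3% ± 2.31 in the replicates (SD, n = 3). Their strongest peaks were in spi, which encodes an EGF receptor ligand (relative signal 4.72), aos, an inhibitor of that receptor (3.68), sog (2.70) and ths, an FGF ligand (2.47). Of 31 proneural and neuroblast genes 10 had a peak (32.3% against 44.6%, adjusted permutation p = 0.36). The leading members were brat (5.26), numb (3.65), N (2.91) and grh (2.79). Genes of neuroblast temporal order and motor neuron identity had a peak less often than length-matched genes. Of these 24 genes 5 had a peak (20.8% against 55.5%, adjusted permutation p = 0.003), with 20.8% ± 4.17 in the replicates (SD, n = 3), and zfh1 (3.60), grh, Lim1 (1.44) and fkh (0.852) led them. The list no longer passed without length matching, where 34.2% was expected (adjusted permutation p = 0.34), nor with the nearest start alone (33.3% against 44.0%, adjusted permutation p = 0.49) or with peaks outside promoters (12.5% against 34.5%, adjusted permutation p = 0.19). Without replicate 1 the share was 12.5% against 50.3% and still passed (adjusted permutation p = 0.0005).

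The other developmental lists did not pass the test with the optimal peaks. Under alternatives, gap and pair-rule genes passed below the expected share with promoter peaks alone (8.70% against 33.5%, adjusted permutation p = 0.03), endoderm, fat body and haemocyte genes below it with the strongest 2904 peaks (5.56% against 31.1%, adjusted permutation p = 0.045), and neuronal differentiation genes above it without length matching (58.6% against 34.2%, adjusted permutation p = 0.023). Peaks were found at 10 of 23 segment polarity genes (43.5% against 50.2%), led by fz (3.14), bowl (2.64), nkd (1.99) and ptc (1.13). The segment polarity share was 26.1% without replicate 1 (45.3% expected) and 26.1% without replicate 2 (42.9% expected). Peaks were at 5 of 23 gap and pair-rule genes (21.7% against 40.0%, adjusted permutation p = 0.19), led by bcd (1.62), tsl (1.52), nanos (1.28) and knrl (0.835). The nanos peak lay at a promoter of the neighbouring gene CG11779, at -81 bp from its start. Of 14 Hox and related genes 7 had a peak (50% against 60%), led by hth (2.03), Antp (1.88), cnc (1.88) and Abd-B (1.28). Of 14 glial genes 7 had a peak (50% against 47.1%), led by moody (6.63), pnt (1.81), loco (1.52) and htl (1.28). Neuronal differentiation genes had peaks at 17 of 29 (58.6% against 61.4%), led by the neuronal RNA-binding protein gene elav (5.35), PlexA (3.13), nSyb (2.72) and side (2.10). The nSyb peak lay at a promoter of the neighbouring gene Bgb, at -135 bp from its start.

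Of 24 mesoderm and muscle genes 13 had a peak (54.2% against 51.96%), led by Mef2 (11.0), kirre (3.23), mbc (2.67) and bin (2.58). The Mef2 peak is the 1 beside Pal1 upstream of Mef2. The mbc peak lay in the neighbouring gene Nup98-96, at 54 bp from its start. Of 18 genes of endoderm, fat body and haemocytes 8 had a peak (44.4% against 47.1%), led by ush (19.8), fkh (0.852), Lsp1beta (0.756) and Hml (0.705). The share of this list was 27.8% without replicate 1 (41.99% expected), 27.8% without replicate 2 (39.6% expected) and 16.7% without replicate 3 (38.9% expected), and none of these passed. Of 21 genes of epidermis, trachea and salivary gland 10 had a peak (47.6% against 51.9%), led by grh, hth, trh (1.79) and tsl. Across all 13968 protein-coding genes 4782 had a peak (34.2%).

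The lists fixed as likely to be unbound in embryos were lower than length-matched genes. Chemosensory receptor genes had peaks at 2 of 36 (5.56% against 28.1%, adjusted permutation p = 0.0086), with 9.26% ± 3.21 in the replicates (SD, n = 3). The 2 were Or88a (relative signal 2.00) and Gr5a (0.676), whose peaks lay nearest to the starts of the neighbouring genes CG12402 and Tre1. The chemosensory call was lost with peaks found in all 3 replicates (5.56% against 22.3%, adjusted permutation p = 0.06), with the nearest start (5.56% against 20.2%, adjusted permutation p = 0.13) and with peaks outside promoters (2.78% against 3.04%, adjusted permutation p = 1.0). Genes of testis, chorion and male accessory gland had peaks at 0 of 29 (0% against 19.6%, adjusted permutation p = 0.022; unadjusted p = 0.0072). This call was lost under 7 alternatives, among them peaks found in all 3 replicates (0% against 15.5%, adjusted permutation p = 0.093).

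**Figure D3:**
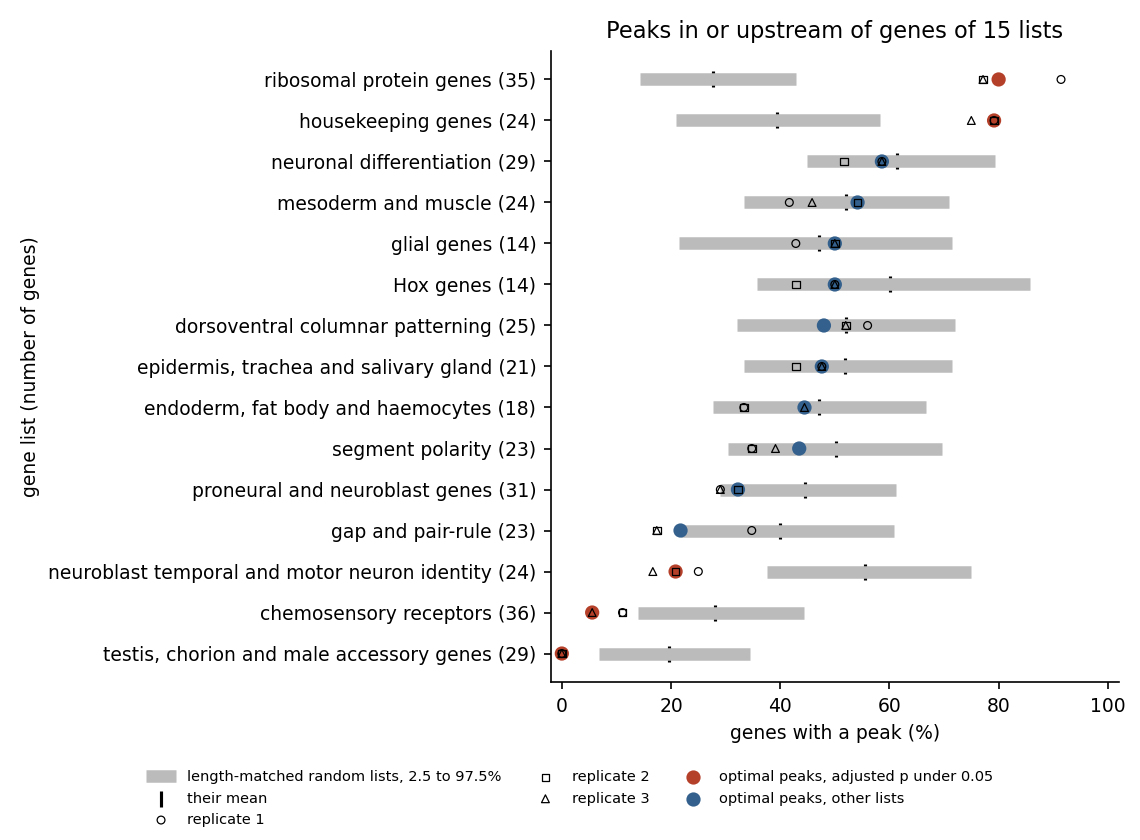
Share of genes with a peak in the gene or 2000 bp upstream (%, horizontal axis) for each of 15 lists (vertical axis, number of genes in parentheses): filled circles are the optimal peaks, red where the adjusted permutation p was under 0.05, open symbols are the replicates, and grey bars are the middle 95% of length-matched random lists with their mean as a tick. Ribosomal protein genes (80.0%) and housekeeping genes (79.2%) lie above the grey bars, and the lists of temporal identity, chemosensory and testis genes lie below them.

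Sequence at the summits was compared with flanks 1000 bp away, with TAATTA, the core bound by many homeodomains, as the motif fixed for ind. TAATTA lay within 100 bp of 18.1% of summits and in 12.3% of flank windows, a difference of 5.76 percentage points ± 0.594 (SE over 5809 peaks) and a ratio of 1.47. The permutation p was 1e-05, the smallest that 100000 resamples can give (adjusted p = 3.3e-05), and the replicates gave a ratio of 1.47 ± 0.0476 (SD, n = 3). The run AAAAAA, fixed as a composition control, had a ratio of 1.53 (48.5% against 31.8%), higher than that of TAATTA. Bases A and T made up 65.0% of the summit windows and 57.4% of the flanks. Of the 36 distinct 6-mers of A and T alone, TAATTA ranked 35 by ratio, with a median ratio of 1.72 for these 36. Among all 2080 6-mers it ranked 194.

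Other fixed 6-mers moved less or the other way. The homeodomain variants TAATTG (ratio 1.14, adjusted permutation p = 0.00042) and TAATGA (1.22, adjusted p = 5e-05) and the caudal-type site TTTATG (1.12, adjusted p = 0.00042) were more frequent at summits. CACCTG, an E-box of the Snail type, was less frequent (5.22% against 8.63%, ratio 0.604, adjusted permutation p = 3.3e-05), as was the Sox-type site ACAATG (0.873, adjusted p = 0.0034). CAGGTA, the core of the Zelda site (0.938, adjusted permutation p = 0.41), GAGAGA, a GAGA factor site (1.10, adjusted p = 0.081), and CATATG (1.10, adjusted p = 0.13) did not pass the permutation test over all peaks. Summit windows held more A and T than flanks (65.0% against 57.4%). These other 6-mers were not compared with shuffled windows, so their changes cannot be told apart from those of base composition.

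Promoter peaks and other peaks were also tested apart, a split made after seeing the data and adjusted over its 20 tests. At the 3017 peaks outside promoters TAATTG (ratio 0.971, adjusted permutation p = 0.56), TTTATG (1.00, adjusted permutation p = 0.94) and ACAATG (0.961, adjusted permutation p = 0.56) no longer passed. CAGGTA was less frequent than in the flanks at promoter peaks (0.680, adjusted permutation p = 0.00066) and more frequent outside promoters (1.28, adjusted permutation p = 0.034). The flanks themselves differed, with CAGGTA in 5.43% at promoter peaks and 3.78% outside, beside 3.69% and 4.84% of summits. The opposite directions therefore cannot be read as loss or gain of Zelda sites at the summits. GAGAGA was more frequent outside promoters (1.23, adjusted permutation p = 0.0038) and did not pass at promoter peaks (0.937, adjusted permutation p = 0.52). The difference between the places was not itself tested.

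The 6-mers with the highest ratios, ranked without a test, were CAGTGT (19.9% of summits against 7.61% of flanks, ratio 2.61), TACACT (2.51) and CACTGT (2.38). At promoter peaks the highest were CGATAG (16.9% against 4.53%, ratio 3.74), TATCGA (3.04) and ATCGAT (2.69). At the 3017 peaks outside promoters they were TACACT (22.1% against 7.71%, ratio 2.87) and GTGCAC (2.72). There TAATTA ranked 494, with a ratio of 1.19, against rank 53 and 1.93 at promoters.

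**Figure D4:**
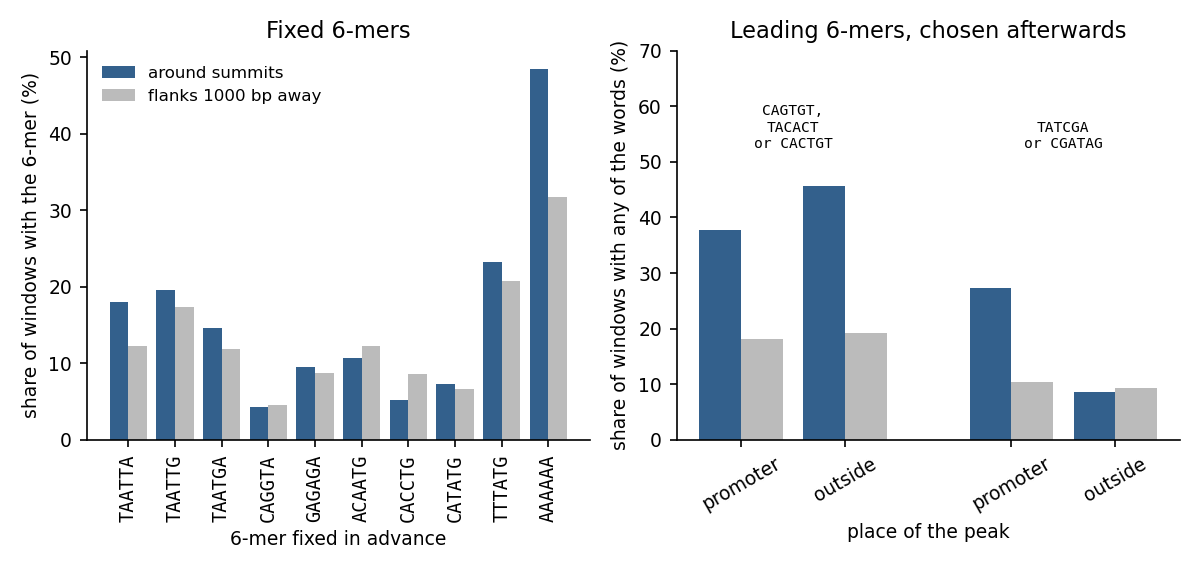
Share of windows (%, vertical axes) holding each of 10 fixed 6-mers (left) or any of the leading 6-mers chosen afterwards (right, at promoter peaks and outside), within 100 bp of the summit in blue and in flanks 1000 bp away in grey. TAATTA stands at 18.1% against 12.3% and AAAAAA at 48.5% against 31.8%, while CAGTGT, TACACT or CACTGT stood in 45.6% of summit windows outside promoters against 19.2% of flanks.

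Neither the share of peaks with TAATTA nor its excess over the flanks passed the test of a difference between strong and weak peaks. TAATTA lay at 17.6% of the strongest and 17.2% of the weakest 1452 peaks, a difference of 0.413 percentage points (permutation p = 0.81), and the replicates gave 1.06 ± 1.19 points (SD, n = 3). Relative to the flanks of the same peaks, its ratio was 1.59 in the strongest 1453 peaks, 1.76 and 1.36 in the next 1452 each and 1.24 in the weakest 1452. The excess over the flanks was 6.51 points in the strongest and 3.34 in the weakest 1452 peaks, a difference of 3.17 points (95% interval -0.0944 to 6.43, permutation p = 0.061), with TAATTA in 11.1% of flanks of the strongest 1453 peaks and 13.9% of flanks of the weakest 1452. The sign of the difference in the share changed with several peak sets, without passing the test in any of the 11 alternatives.

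Short, highly transcribed loci were examined as places where ChIP signal can arise without the tagged protein. Within 500 bp of 801 genes for tRNA, snRNA, snoRNA, rRNA or histones lay 26 summits, 0.448% against 0.437% of shifted summits (permutation p = 0.93), with 0.499% ± 0.199 in the replicates (SD, n = 3). The tRNA genes had 13 (ratio 1.31), the snoRNA genes 10 (1.35) and the snRNA genes 3 (1.91), and the 99 rRNA and 111 histone genes had 0. How reads from repeated genes were placed is not given in the sources used here. The 0 of these 2 classes is therefore weak evidence, and it lowers the joint share. None of these classes passed the test (adjusted permutation p = 0.49 for each). Within 1000 bp of these genes the share was 1.17% against 0.665% (permutation p = 0.002). The bodies of housekeeping genes held 14 summits, 0.241% against 0.0808% (ratio 2.98, adjusted permutation p = 0.056), and those of ribosomal protein genes 6 (ratio 2.24, adjusted permutation p = 0.26).

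Few strong peaks were confined to a single replicate by a loose match to the full relaxed lists. Those lists are long and include background, and no chance rate was computed for this match, so the low counts say little about agreement. Replicate 1 had 166 peaks among its 5809 strongest (2.86%) with no summit within 500 bp in the full lists of the other replicates, and 68.1% of them were at promoters. The strongest were at CG14805 (relative signal 1.54, rank 1451) and CG13751 (1.35). Replicate 2 had 10 such peaks, the strongest at CG7328 (0.868) and in an intron near Lztr1 (0.648), and replicate 3 had 1, at CG8858 (0.619).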

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

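The pooled relaxed list holds 18435 peaks below the authors' threshold that the comparisons of the optimal list do not use, and their location was examined only after the main results were seen. Of these weaker summits 23.2% lay within 500 bp of a transcription start, against 13.6% of shifted summits (permutation p = 0.005, the smallest that 200 shifts can give). It is listed here because it is a signal above chance in peaks outside the optimal list, and it was put on the list after its value had been seen. The share was lower than the 48.1% of the optimal peaks. TAATTA was not more frequent at these summits than in their flanks (13.6% against 13.9%, permutation p = 0.37), and 4.03% of them lay in coding sequence.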

How the results depend on the processing

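The alternatives limited to promoter peaks, to peaks outside promoters and to 1 peak per 500 bp were chosen after the main results were seen. The promoter share stayed above shifted summits under every alternative run (37.6% to 58.6%; 48.4% to 51.6% without a replicate). The excess of TAATTA over the flanks stayed above 0 and past the test (2.87 to 8.88 points), as did the X density ratio above 1 (1.13 to 1.21). Every alternative of the X ratio kept the same full arm lengths. Replicate overlap was 70.3% where intervals had to overlap by 50% of both and 98.8% against all peaks of each replicate, as the constructions of a stricter and a looser match give, and 85.0% to 90.5% without a replicate. The rank correlation ran from 0.772 without replicate 3 to 0.868 without replicate 1. The number of lists above length-matched genes was 2, or 0 with peaks outside promoters, 1 with the nearest start and 3 with no length matching. Of 165 list values under alternatives, 121 kept their direction and side of the threshold, 15 kept their direction and lost a call, 2 gained one (gap and pair-rule genes, 8.70% with promoter peaks alone, and endoderm genes, 5.56% with the strongest 2904 peaks) and 27 changed direction, of which 1 passed the test (neuronal differentiation, 58.6% with no length matching, adjusted permutation p = 0.023). Dorsoventral columnar genes changed direction at 36% (strongest 2904 peaks), 44% (found in all 3 replicates), 44% (outside promoters), 60% (nearest start) and 48% (no length matching), and stood at 44% without any 1 replicate, on the other side of the expected share only without replicate 3. Epidermis, trachea and salivary gland genes did so at 38.1%, 42.9%, 38.1%, 52.4% and 47.6% in the same order, and stood at 42.9% to 47.6% without a replicate, changing direction without replicate 2 (47.6%). With promoter peaks alone glial genes (35.7%) and mesoderm genes (33.3%) changed direction, and within 1000 bp of a start mesoderm genes (25%). With peaks outside promoters it changed for proneural (29.0%), segment polarity (34.8%), gap and pair-rule (17.4%), endoderm (38.9%) and ribosomal protein genes (2.86%), which also lost their call. With the nearest start it changed for segment polarity (47.8%), Hox (50%) and endoderm genes (55.6%), and with no length matching for segment polarity (43.5%), Hox (50%) and endoderm genes (44.4%). TAATTA by peak strength turned to -2.07 points (strongest 2904 peaks), -1.28 (found in all 3 replicates), -1.33 (outside promoters) and -2.89 (250 bp windows), and to between -1.97 and -0.0827 without a replicate. It was 3.87 points with promoter peaks (permutation p = 0.068) and 1.93 with 50 bp windows (permutation p = 0.093), and no alternative passed the test. The share near technical loci lay below that of shifted summits at 0.393% (found in all 3 replicates), 0.241% (within 250 bp) and 0.0331% (outside promoters, permutation p = 0.017). It passed the test above them at 0.895% (promoter peaks, permutation p = 0.014) and 1.17% (within 1000 bp), and was 0.372% to 0.479% without a replicate, below shifted summits without replicate 1 (0.372% against 0.435%) and without replicate 3 (0.398% against 0.442%). The promoter split is partly fixed by construction, since starts of these loci count as promoters, and the cause was not tested for the other changes. The planned list of the strongest pooled peaks was the optimal list itself and gave no value of its own, and peaks per arm in dm3 were run only as the X share (20.2% against 20.1% in dm6). Depth is unknown, so whether weak sites were missed in a replicate for lack of reads cannot be judged.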

Other observations

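The gene families, promoter layouts and sequence words in this part were chosen after the main results were seen. Of 22 families taken by gene symbol, 4 had more genes with a peak than length-matched genes and 9 had fewer, by the same test adjusted over the families. Peaks stood at 65 of 92 cytoplasmic ribosomal protein genes (70.7% against 24.6%, adjusted permutation p = 0.00031) and at 41 of 73 mitochondrial ribosomal protein genes (56.2% against 20.6%, adjusted permutation p = 0.00031). Nucleoporin genes (14 of 21, 66.7% against 38.0%, adjusted permutation p = 0.015) and respiratory chain genes (33 of 86, 38.4% against 24.5%, adjusted permutation p = 0.0071) were also above. Proteasome genes (35.4% against 25.9%, adjusted permutation p = 0.17) and translation initiation factors (38.6% against 34.5%, adjusted permutation p = 0.62) did not pass. Genes with a peak were fewer among cuticle protein genes (3 of 96) and cytochrome P450 genes (8 of 85). The same held for ionotropic receptors (2 of 60) and odorant receptors (2 of 59). The adjusted permutation p was 0.00031 for each of these families. Among neuronal families, dpr and DIP adhesion genes were below (9 of 32, 28.1% against 60.2%, adjusted permutation p = 0.00055).

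Genes with a peak within 500 bp of their start were more often arranged head to head. Of 3030 such genes 62.0% had a neighbour on the other strand starting within 1000 bp upstream, against 25.3% of the other 10938 genes, and 34.5% in length-matched sets (permutation p = 0.0001, the smallest possible). A summit between such starts can count for both genes, which raises these shares by construction. With each summit given to the nearest start alone, the share was 48.9% of 2123 genes with a peak against 34.3% in length-matched sets (permutation p = 0.0001, the smallest possible). Of the ribosomal protein genes in the list 65.7% were so arranged, as were 50% of the housekeeping genes and 0% of the proneural genes. Matched on this layout and on length, ribosomal protein genes still had a peak more often (80.0% against 37.1%). Housekeeping genes did too (79.2% against 42.3%, permutation p = 0.0001 for each list, the smallest possible). Promoter summits nearest to a coding start had a median position of -113 bp from it, and 86.5% of 2654 were upstream. Outside promoters, the genes with most summits were kirre (19), CG1677 (17), shn (14), sbb (13), CHES-1-like (11), Raf (11) and ush (11). The counts are not corrected for gene length: kirre spans 394 kb and CHES-1-like 27.0 kb.

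Longer words were ranked at promoters and outside them separately, without a test between the places. At promoters TATCGATA, the core of the DNA replication-related element, lay at 7.56% of summits and 0.466% of flanks. Outside promoters CACTGAGA lay at 6.36% of summits against 0.530% of flanks, and CAGTGTAC at 3.45% against 0.331%. Any of CAGTGT, TACACT or CACTGT stood at 45.6% of summits outside promoters and 37.7% at promoters, against 19.2% and 18.1% of flanks. TATCGA or CGATAG stood at 27.3% of promoter summits against 10.3% of flanks, and outside promoters at 8.65% against 9.40% (permutation p = 0.24). CAGTGT was 2.73 times as frequent at summits as in copies of the same windows shuffled with their dinucleotides kept.

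The tests on transcription and on peak strength in the next paragraphs were chosen after their results had been seen, the others before. The peaks at ribosomal protein and housekeeping genes were set against technical sources. Base composition of the promoters did not account for them, since 76.3% of the 59 genes had a promoter peak in the gene or 2000 bp upstream, at their own start or another, against 31.5% in lists matched on G and C content, whose middle 95% ended at 44.1%. Heavy transcription stays open: the median rank of ribosomal protein promoter peaks was 272 places below that of other promoter peaks, which did not pass the test in either direction (permutation p = 0.61), and the lists hold no expression values. A CGATAG or TATCGA element was also examined. It stood near the start of 51.1% of the 45 list genes with such a peak and of 32.9% of genes without a peak. The difference was 18.2 percentage points (permutation p = 0.011). The share was 59.3% of 27 ribosomal protein and 38.9% of 18 housekeeping genes, beside 46.3% of all 3971 genes with such a peak. The element had been chosen because it led the ranking at promoter peaks of this list, so the test is not independent of that choice. The housekeeping share lies closer to that of genes without a peak. The test also took only list genes that already had such a peak, and genes with such a peak carried the element more often in general. It therefore cannot say why these lists exceeded other genes.

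The excess of TAATTA may come from the base composition of the peaks. In summit windows TAATTA was 0.904 times as frequent as in shuffled copies that keep the dinucleotides, and in flanks 1.21 times, so the ratio between them was 0.745 ± 0.0308 (bootstrap SE), below 1. If homeodomain binding raised the signal, stronger peaks would carry TAATTA more often. The share itself differed by 0.413 points between the strongest and the weakest 1452 peaks (95% interval -2.35 to 3.17), but the excess over the flanks differed by 3.17 points (95% interval -0.0944 to 6.43, permutation p = 0.061), which neither shows such a rise nor excludes one as large as the excess of all peaks (5.76 points). Against shuffled copies TAATTA had no excess at summits, so base composition alone can give its excess over the flanks. Whether homeodomain binding adds to the signal of some peaks stays open. TAATTA had no excess below the threshold (13.6% against 13.9%). The ranking of A and T words above TAATTA had been seen before the shuffling was run.

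The lack of an excess at neural patterning genes might come from a threshold that leaves weak sites out. Below the threshold, 67.3% of the 55 genes of the columnar and neuroblast lists had a pooled peak, against 67.0% in length-matched lists whose middle 95% ended at 76.4%. The share lay close to the mean of those lists and within their range, so it gave no sign of weak sites left out. It was not at or below that mean, the condition set in advance against a threshold effect, so the effect was not excluded. Apart, columnar genes stood at 80% against 72.9% and neuroblast genes at 58.1% against 61.3%. Temporal and motor neuron identity genes, outside this test, stood at 58.3% against 77.4% (adjusted permutation p = 0.1). No biological explanation was tested for the lack of an excess, and in whole embryos binding limited to few cells may go unseen.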
